A study of Mus musculus with 28 samples.

How the data were processed

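RNA from mouse thymocytes was measured by RNA sequencing in 28 samples. The labels give 3 genotypes (wild type, Lmo2tg, and Lmo2tg; Ldb1-KO) and 2 sorted subsets, DN2/3 and DN4, which are successive stages of thymocytes that carry neither CD4 nor CD8 on their surface. The group Lmo2tg; Ldb1-KO, which carries the Lmo2 transgene and a deletion of Ldb1, is called Ldb1-KO here. The labels also call the cells CD4 T cells, while the subset names are those of double-negative thymocytes. The series design text states 4 Ldb1-KO replicates per stage, and the sample labels, which give 5, were followed. The growth protocol names several Cre lines, and which was used in each Ldb1-KO sample is not given in the sources used here. Nothing in the labels states that replicates came from separate animals, so the p-values measure the spread between these samples.

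Per the labels, libraries were made with a TruSeq V2 RNA kit and sequenced as paired-end reads of 101 bases on a HiSeq2500. The submitters' processing notes name alignment to mm10 with STAR 2.5.2a and read counting with featureCounts 1.4.6-p3. The values the authors deposited are raw counts per gene symbol, whole numbers in every cell, with 24421 symbols. The annotation, the strand setting and the handling of reads that match more than 1 place are not given in the sources used here. With the strand setting unknown, reads of a gene that overlaps another on the opposite strand could be counted for either. Reads that match near-identical genes could be dropped or kept. Each column of the table was joined to its sample by the library name in the sample description, and 0 columns were left without a sample. The names of the wild-type libraries follow another pattern than those of the transgenic libraries, so library series and genotype split the samples in the same way. Any technical difference between the series cannot be separated from a difference between wild type and the transgenic groups.

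Total counts per library ran from 28.1 to 106.9 M counts. No pair of replicates was a copy of another: the lowest chi-square per degree of freedom between replicates was 28.5. Of the symbols, 23384 matched a gene name of GENCODE M21, from which positions on mm10 were taken.

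Counts were fitted in R 4.3.3 with edgeR 4.0.16. A single quasi-likelihood model held the 28 samples as 6 groups, with TMM normalization, the filterByExpr filter by group (14371 genes kept) and robust dispersion. Each contrast was tested with the quasi-likelihood F-test, two-sided, and p-values were adjusted by Benjamini-Hochberg over the genes tested in it. A gene is called changed at an adjusted p below 0.05. The 11 contrasts are Lmo2tg against wild type, Ldb1-KO against Lmo2tg and Ldb1-KO against wild type at each stage, DN4 against DN2/3 in each genotype, and the difference between stages in the Lmo2tg effect and in the Ldb1-KO effect. Levels are CPM, counts per M counts of the library, with TMM-scaled library sizes. Log2 fold changes come from the same model. For a gene with no count in any library of a group, the fold is given as a lower bound against a floor of 3 counts over the group.

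Named genes were chosen by a rule fixed before the data were examined. In the 4 main comparisons (Lmo2tg against wild type and Ldb1-KO against Lmo2tg at each stage) these were Lmo2 and Ldb1, the 6 largest rises and 6 largest falls among changed genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' samples, and from each of 11 gene lists the 2 members with the smallest adjusted p. In a list without a changed member, the member with the highest CPM was taken. Other contrasts took Lmo2, Ldb1 and the 3 largest changes in each direction. Predicted or unnamed genes and receptor segments were left out, and a few other genes that the rule picks are not reported here. A few further list members were named after their values were seen, and this is stated beside them.

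The gene lists were also written before the data were examined. The main lists were Lmo2-Ldb1 complex genes (Lmo2, Ldb1 and partners), stem and progenitor regulators, T-lineage commitment and pre-TCR, Notch targets, cell cycle, cell cycle inhibitors, Bcl2 family, cytokine receptors, Myc and ribosome biogenesis, glycolysis, and interferon response. Markers of other cells that the gate could hold were B cell, myeloid, mast cell and basophil, NK and innate lymphoid, dendritic, gamma-delta T, double-positive thymocyte, mature T, erythroid, megakaryocyte, thymic stroma, immediate early and heat shock, and sex genes. A list of mitochondrially encoded genes had no member in the table and was not tested. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 between genes, two-sided, and adjusted over the 24 lists within a contrast. Some lists overlap: Lyl1, Tal1 and Gata2 stand in both the partner and the stem list, Rag1, Rag2, Themis and Dntt in both the T-lineage and the double-positive list. The genes Trdc, Trac and Scart2 were not found under their symbols.

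Libraries with the same replicate number were checked for pairing. After group means were removed, each library correlated best with its own number at the other stage (r of 0.51 to 0.65 in Lmo2tg, 0.29 to 0.53 in Ldb1-KO and 0.15 to 0.33 in wild type), and sex-linked transcripts matched. Tests between stages were therefore also run with the genotype-by-number pair as a block. Between Lmo2tg and Ldb1-KO, 2 of 5 numbers matched best per stage, with wild type 0.

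The alternatives were RLE normalization, no count filter, a filter of 1 CPM in at least 4 samples, DESeq2 1.42.0, a model of the compared groups only, the replicate block, leaving out each replicate in turn, an estimated correlation and fry for lists, and a split of the Lmo2tg libraries for shared-group comparisons. Some were added after seeing the data: genes that share at least 10% of their 101-base stretches with another gene left out, Lmo2 and Ldb1 left out of the lists, and 2 DN4 libraries high in Cd4 and Cd8a left out. Shared sequence was measured on GENCODE M21 transcripts, on a sample of 1 in 4 of the distinct stretches, as the share of a gene's stretches that also occur on either strand in a gene elsewhere in the genome, with a value for 91.4% of the genes in the table. The model was tested on simulated data (these group sizes, 200 changed genes, 1 spread per gene for all groups). It recovered 36.4 to 43.9% of 1.5-fold, 60.6 to 63.6% of 2-fold and 84.6 to 90.6% of 4-fold changes, with 3 to 6 false calls per comparison. Simulated lists (1 comparison with, 1 without a shift) had 0 false calls, but with uncorrelated genes.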

Results

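Messenger RNA levels were measured by RNA sequencing in mouse thymocytes of 3 genotypes. Lmo2, a LIM-only adaptor protein and T-cell leukemia oncogene, was expressed from a transgene in the Lmo2tg and Ldb1-KO samples. Ldb1, a LIM domain-binding cofactor that forms a complex with Lmo2, was by label deleted in the Ldb1-KO samples, which the labels call Lmo2tg; Ldb1-KO. Cells were sorted as DN2/3 and DN4, early and later thymocytes without surface CD4 or CD8. Each stage had 4 wild-type, 5 Lmo2tg and 5 Ldb1-KO libraries, 28 in all. Median totals ran from 45.85 (Lmo2tg DN4) to 74.36 M counts (wild type DN2/3). Values are CPM as mean ± SD of these libraries, and fold changes (log2 fold) and adjusted p-values are from the edgeR model of 14371 genes. For lists of genes the adjusted p is that with a preset correlation between genes, and the value after "estimated" is the adjusted p with the correlation estimated from the data.

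Lmo2 was raised in both transgenic groups, and Ldb1 transcript was lowered, not lost, in Ldb1-KO. Lmo2 (mm10 chromosome 2, 103957986 to 103981878) had 0.272 ± 0.105 CPM in wild type DN2/3 and 0.0778 ± 0.0708 CPM in wild type DN4. It had 32.6 ± 3.8 and 45.1 ± 13.5 CPM in Lmo2tg and 30.5 ± 7.43 and 45.4 ± 6.66 CPM in Ldb1-KO. Lmo2 rose in Lmo2tg over wild type at DN2/3 (log2 fold 6.91, SE 0.34, adjusted p = 4.04e-14). It rose at DN4 as well (log2 fold 9.13, SE 0.40, adjusted p = 2.46e-15). No difference in Lmo2 passed the test between Ldb1-KO and Lmo2tg at either stage (adjusted p = 0.825 and 0.986). Ldb1 (chromosome 19, 46031570 to 46045214) had 511 ± 39.5 and 358 ± 18 CPM in wild type and 397 ± 58 and 345 ± 72.2 CPM in Lmo2tg, with no change that passed the test (adjusted p = 0.472 and 0.91), though that at DN2/3 did in a model of the compared groups only (0.0418). It fell in Ldb1-KO to 98.1 ± 26.9 CPM at DN2/3 (log2 fold -2.02, SE 0.34, adjusted p = 0.000103). At DN4 it fell to 25.7 ± 19.3 CPM (log2 fold -3.75, SE 0.37, adjusted p = 1.53e-07). These levels are 24.7% and 7.43% of those in Lmo2tg, with single libraries from 57.1 to 120 CPM at DN2/3 and from 6.11 to 54.7 CPM at DN4.

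**Figure D1:**
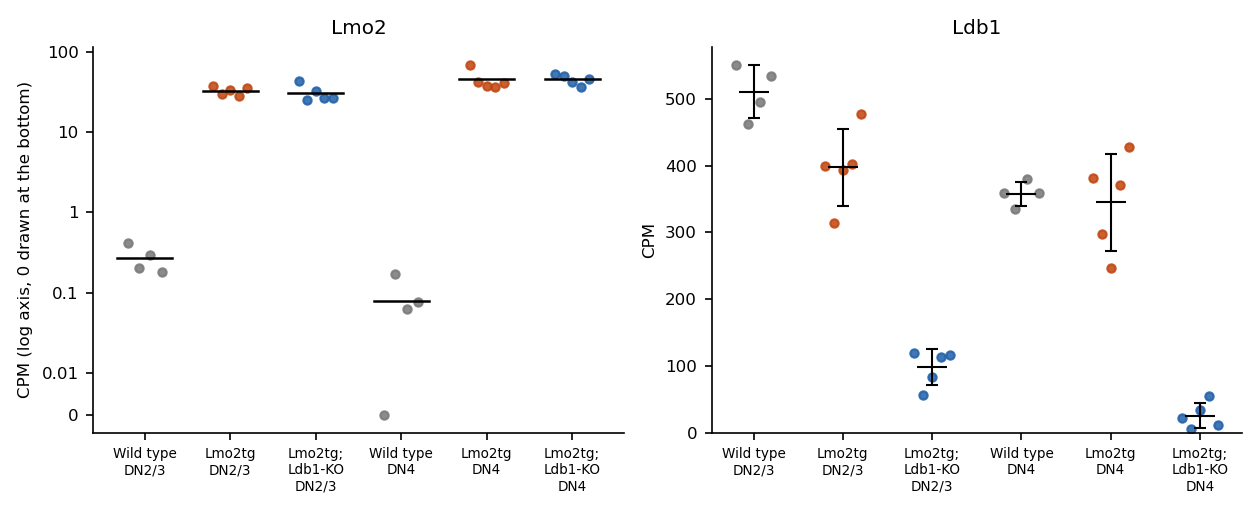
CPM of Lmo2 (log axis, libraries at 0 drawn at the bottom, line at the mean) and of Ldb1 (linear axis, mean ± SD) in each library of the 6 groups.

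Lmo2tg against wild type at DN2/3 asks what the transgene changes in early thymocytes. The calcium release channel gene Ryr2, the organic cation transporter gene Slc22a4 and the basic helix-loop-helix gene Lyl1 rose, while the homeobox gene Hoxa7, the kinase inhibitor gene Cdkn1a and the pre-TCR gene Ptcra fell. Hoxa7 went from 13 ± 0.922 CPM in 4 wild-type libraries to 0.0488 ± 0.0581 CPM in 5 Lmo2tg libraries (log2 fold -8.15, SE 0.65, adjusted p = 4.3e-10), without overlap. In all, 4242 genes changed, 2175 higher and 2067 lower in Lmo2tg, of which 1093 and 1109 by over 2-fold.

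Among the largest rises, Ryr2 had no count in wild type and 20.2 ± 12.7 CPM in Lmo2tg, at least 2210-fold higher against a floor of 3 counts over the wild-type group (adjusted p = 1.82e-06). The potassium channel subunit gene Kcns3 had 8.6 ± 3.83 CPM against no count, at least 938-fold higher (adjusted p = 1.89e-05). Thsd4 had no count in wild type and 8.91 ± 15.7 CPM in Lmo2tg, at least 971-fold higher (adjusted p = 0.00723), with replicate 5 at 36.7 CPM and the others from 0.0549 to 5.87. Slc22a4 rose to 28.5 ± 5.55 against 0.0205 ± 0.0321 CPM (log2 fold 10.62, SE 0.88, adjusted p = 3.2e-09). Pof1b rose to 31.3 ± 34.7 against 0.0146 ± 0.0177 CPM (log2 fold 10.61, SE 1.99, adjusted p = 0.000268). Sobp had 2 counts over the wild-type group and 12.6 ± 5.36 against 0.00447 ± 0.00894 CPM (adjusted p = 5.05e-06).

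The largest falls included Hoxa7 (chromosome 6, 52214491 to 52221854). Kazn, which encodes kazrin, fell to 0.011 ± 0.0151 against 13.2 ± 0.958 CPM (log2 fold -9.69, SE 0.71, adjusted p = 9.28e-11). Mira, a noncoding RNA of the Hoxa cluster, fell to 0.0202 ± 0.0451 against 11.1 ± 1.6 CPM (log2 fold -8.70, SE 0.69, adjusted p = 3.73e-10). Ica1 fell to 0.0226 ± 0.0375 against 7.99 ± 1.54 CPM (log2 fold -8.08, SE 0.62, adjusted p = 2.3e-10). Msantd3 fell to 0.042 ± 0.028 against 7.16 ± 1.49 CPM (log2 fold -7.52, SE 0.52, adjusted p = 2.96e-11).

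Of 25 measured stem and progenitor regulators at DN2/3, 5 rose and 12 fell in Lmo2tg (5 and 13 adjusted over the list alone). The list was lower as a group (adjusted p = 0.0441, estimated 0.574), and it alone of the 24 lists passed in this comparison. The call ended without Lmo2tg DN2/3 replicate 4 (adjusted p = 0.0764) or 5 (0.0618). Without Lmo2tg DN2/3 replicate 1, the cell cycle (adjusted p = 0.0274), inhibitor (0.0443), glycolysis (0.0443), interferon (0.0376) and immediate early lists (0.0443) passed too, the last also without wild type DN2/3 replicate 3 (0.027). Of 18 Lmo2-Ldb1 complex genes 7 rose, 1 of them Lmo2, and 3 fell (adjusted p = 0.0877, and 0.692 for the list without Lmo2 and Ldb1). Lyl1 rose to 72.6 ± 29.7 against 6.17 ± 1.01 CPM (log2 fold 3.55, SE 0.61, adjusted p = 7.28e-05). T-lineage and pre-TCR genes went both ways, 9 higher and 9 lower of 26 (adjusted p = 0.9). Cd3g, a chain of the T-cell receptor complex, fell to 491 ± 65.8 against 1340 ± 88.7 CPM (log2 fold -1.45, SE 0.12, adjusted p = 5.36e-10). The surface receptor gene Cd6 rose to 158 ± 4.66 against 39.9 ± 7.96 CPM (log2 fold 1.98, SE 0.21, adjusted p = 6.97e-08). Of 12 Notch targets 2 rose and 3 fell (adjusted p = 0.898). Trib2 rose to 90.8 ± 26.8 against 14 ± 1.39 CPM (log2 fold 2.69, SE 0.24, adjusted p = 2.81e-09). Ptcra fell to 31.7 ± 8.98 against 177 ± 14.7 CPM (log2 fold -2.48, SE 0.29, adjusted p = 2.25e-07).

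Cell cycle inhibitors had 7 rises and 2 falls among 14 (adjusted p = 0.0877). Cdkn1a fell to 2.77 ± 1.64 against 58.8 ± 9.17 CPM (log2 fold -4.41, SE 0.42, adjusted p = 1.16e-08). Cdkn2d rose to 55.2 ± 5.54 against 27.6 ± 2.79 CPM (log2 fold 1.00, SE 0.14, adjusted p = 4.29e-06). Of 33 cell cycle genes 2 rose, and 0 when adjusted over the list alone (adjusted p = 0.139). The cyclin gene Ccnb1 had 96 ± 40.7 against 49.4 ± 3.93 CPM (log2 fold 0.96, adjusted p = 0.0116). The centromere gene Cenpf had 92.6 ± 29.3 against 59.9 ± 8.33 CPM (log2 fold 0.63, adjusted p = 0.0196). The call on Cenpf ended without wild type DN2/3 replicate 1 (adjusted p = 0.0742) or 2 (0.0511) or Lmo2tg DN2/3 replicate 2 (0.0857). In the Bcl2 family 3 rose and 3 fell of 15 (adjusted p = 0.898). The survival gene Bcl2l2 fell to 13.8 ± 5.3 against 32.2 ± 2.03 CPM (log2 fold -1.22, adjusted p = 0.000153). Bbc3, which encodes the cell death protein Puma, rose to 20.8 ± 5.85 against 8.03 ± 0.861 CPM (log2 fold 1.37, adjusted p = 0.00102).

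Cytokine receptors had 4 rises and 5 falls among 24 (adjusted p = 0.898). Csf2ra, the GM-CSF receptor alpha chain, fell to 3.72 ± 3.32 against 40.9 ± 3.37 CPM (log2 fold -3.47, adjusted p = 3.41e-06). Il17rb fell to 142 ± 33.8 against 299 ± 29.2 CPM (log2 fold -1.07, adjusted p = 0.000137). Glycolysis genes had 7 rises among 17 (adjusted p = 0.0877). The enzyme gene Pgk1 rose to 388 ± 78.9 against 193 ± 14.3 CPM (log2 fold 1.01, adjusted p = 1.53e-05). Pfkp rose to 85 ± 22.6 against 42.8 ± 3.67 CPM (log2 fold 0.99, adjusted p = 0.000317). Pgk1 shares 51.8% of its 101-base stretches with other genes and Ccnb1 14.3%, so their values against wild type are uncertain.

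Interferon response genes had 4 falls among 20 (adjusted p = 0.0877). Ifi44 fell to 0.0384 ± 0.0529 against 6.56 ± 2.03 CPM (log2 fold -7.07, adjusted p = 4.31e-07). The RNA sensor gene Ifih1 fell to 14.4 ± 4.14 against 37.2 ± 6.41 CPM (log2 fold -1.37, adjusted p = 0.00592). Among 21 Myc and ribosome biogenesis genes only Bop1 passed (201 ± 37.7 against 131 ± 18 CPM, log2 fold 0.61, adjusted p = 0.0394, and adjusted p = 0.898 for the list). Its call ended without wild type DN2/3 replicate 2 (adjusted p = 0.126), 3 (0.0792) or 4 (0.0658) or Lmo2tg DN2/3 replicate 2 (0.102), 3 (0.0529) or 4 (0.0845). Over all 11 contrasts, 37 of 264 list results had a median, mean or test of differing sign, and 0 of these passed the test.

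At DN4, Lmo2tg against wild type asks the same of the later stage. The homeobox gene Hhex, Lyl1, the stem cell factor receptor gene Kit and the interferon-induced genes Mx1 and Mx2 rose, and Myc fell. Falls passed in 28 of 33 cell cycle genes (30 adjusted over the list alone, adjusted p = 3.21e-07, estimated 0.405) and 17 of 21 ribosome biogenesis genes (18, adjusted p = 1.96e-05, estimated 0.405), and neither call held when estimated. Cd4 (113 against 6.33 CPM) and Cd8a (343 against 33.6 CPM), which mark later cells, were also higher, most so in Lmo2tg DN4 replicate 1 (422 and 742 CPM). Hhex went from 0.0849 ± 0.12 CPM in 4 wild-type libraries to 65.6 ± 55.3 CPM in 5 Lmo2tg libraries (log2 fold 9.65, SE 1.04, adjusted p = 9.35e-08). Lyl1 went from 0.303 ± 0.17 to 39.1 ± 27.2 CPM (log2 fold 6.99, SE 0.77, adjusted p = 1.21e-07). In all, 7532 genes changed, 4148 higher and 3384 lower, of which 2359 and 667 by over 2-fold. The count was 4947 in a model of the compared groups only, and the cause was not tested.

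Among the largest rises Ryr2 had no count in wild type and 65.8 ± 57.1 CPM in Lmo2tg, at least 6150-fold higher (adjusted p = 5.02e-07). Pof1b was at least 4690-fold higher (50.3 ± 74.1 CPM, adjusted p = 8.7e-05). Ubqlnl was at least 1360-fold higher (14.6 ± 13.9 CPM, adjusted p = 3.39e-06). Faxc was at least 816-fold higher (8.74 ± 5.01 CPM, adjusted p = 2.14e-05). Thsd4 was at least 1310-fold higher (14 ± 28.8 CPM, adjusted p = 0.00328), with replicate 5 at 65.5 CPM and the others from 0.178 to 3.62. Hoxa7 fell to 0.0599 ± 0.0748 against 6.65 ± 0.81 CPM (log2 fold -6.94, SE 0.63, adjusted p = 5.67e-09). Mira fell to 0.0193 ± 0.0432 against 7.49 ± 1.41 CPM (log2 fold -8.15, SE 0.69, adjusted p = 1.81e-09). Arhgap32 fell to 0.0873 ± 0.0835 against 16.4 ± 0.542 CPM (log2 fold -7.45, SE 0.62, adjusted p = 1.46e-09). The phospholipase gene Pla2g4a fell to 0.193 ± 0.181 against 15.7 ± 3.12 CPM (log2 fold -6.33, SE 0.56, adjusted p = 3.94e-09). Msantd3 had 2 counts over the Lmo2tg group, at 0.00696 ± 0.0156 against 6.01 ± 0.702 CPM (adjusted p = 1.4e-11).

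Among cell cycle genes at DN4, the cyclin gene Ccne1 fell to 38 ± 13.8 against 88.1 ± 9.31 CPM (log2 fold -1.22, SE 0.22, adjusted p = 7.91e-05). Tyms, which serves nucleotide synthesis, fell to 109 ± 38.3 against 240 ± 29.8 CPM (log2 fold -1.14, SE 0.21, adjusted p = 0.000103). Myc fell to 220 ± 94 against 452 ± 48.5 CPM (log2 fold -1.04, SE 0.19, adjusted p = 8.4e-05). Dkc1 fell to 194 ± 51.3 against 311 ± 18.7 CPM (log2 fold -0.68, SE 0.14, adjusted p = 0.000314). Cell cycle inhibitors had 10 rises and 2 falls among 14 (adjusted p = 0.00149, estimated 0.113). Btg1 rose to 380 ± 223 against 45.2 ± 10.5 CPM (log2 fold 3.07, SE 0.34, adjusted p = 1.16e-07). Cdkn1b rose to 136 ± 32.8 against 54.4 ± 9.66 CPM (log2 fold 1.33, SE 0.15, adjusted p = 2.66e-07). Glycolysis genes had 3 rises and 9 falls (adjusted p = 0.12). The lactate transporter gene Slc16a3 rose to 8.65 ± 5.99 against 1.48 ± 0.39 CPM (log2 fold 2.54, adjusted p = 3.48e-06). Pfkl fell to 81.1 ± 32.8 against 162 ± 26.1 CPM (adjusted p = 0.000376).

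Complex genes had 9 rises, Lmo2 itself among them, and 2 falls (adjusted p = 0.0477, estimated 0.298), and the list did not pass without Lmo2 and Ldb1 (0.371). Stem and progenitor regulators had 10 rises and 4 falls and did not pass as a list (adjusted p = 0.0853), though they did without Lmo2tg DN4 replicate 2 (0.0482) or 3 (0.0487). T-lineage genes had 13 rises and 4 falls (adjusted p = 0.104). Thy1 fell to 1040 ± 281 against 2060 ± 179 CPM (log2 fold -0.98, adjusted p = 2.08e-06). Cd5 rose to 207 ± 132 against 35.3 ± 7.34 CPM (log2 fold 2.55, adjusted p = 2.78e-06). Notch targets had 6 rises and 2 falls (adjusted p = 0.192). Heyl rose to 5.6 ± 1.89 against 0.833 ± 0.227 CPM (log2 fold 2.75, adjusted p = 3.95e-08). Trib2 rose to 145 ± 56.5 against 33 ± 2.48 CPM (log2 fold 2.13, adjusted p = 1.03e-07).

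Cytokine receptors had 15 rises and 3 falls (adjusted p = 0.0448, estimated 0.405). The call ended without wild type DN4 replicate 1 (adjusted p = 0.0517) or 4 (0.0532) or Lmo2tg DN4 replicate 1 (0.0578). Kit rose to 113 ± 68.2 against 21.5 ± 3.97 CPM (log2 fold 2.39, adjusted p = 2.82e-06). Tgfbr2 rose to 77.9 ± 37.7 against 22.3 ± 4.03 CPM (log2 fold 1.81, adjusted p = 3.33e-06). In the Bcl2 family 8 rose and 3 fell (adjusted p = 0.101), and the list passed without Lmo2tg DN4 replicate 3 (0.0456). The cell death gene Bmf rose to 54.9 ± 13.4 against 19.9 ± 3.71 CPM (log2 fold 1.46, adjusted p = 7.91e-07). Bbc3 rose to 21.5 ± 8.65 against 4.04 ± 0.871 CPM (log2 fold 2.41, adjusted p = 1.66e-06). Interferon response genes had 12 rises and 2 falls (adjusted p = 0.106), and passed without Lmo2tg DN4 replicate 2 (0.0499) or 4 (0.0191). The antiviral gene Mx1 rose to 10.2 ± 8.83 against 0.872 ± 0.168 CPM (log2 fold 3.55, adjusted p = 3.34e-05). Its relative Mx2 rose to 6.8 ± 4.72 against 1.21 ± 0.272 CPM (adjusted p = 6.57e-05).

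Of the markers of other cells in Lmo2tg DN4, B cell markers had 11 rises among 12 (adjusted p = 0.00548, estimated 0.405). Mature T cell markers had 10 among 12 (adjusted p = 0.000333, estimated 0.298). Immediate early and heat shock genes had 12 among 15 (adjusted p = 0.000154, estimated 0.405). Other marker lists did not pass as lists. Of these, myeloid markers had 9 rises among 13 (adjusted p = 0.0559), NK and innate lymphoid 8 of 12 (0.0601) and dendritic 5 of 9 (0.191). Myeloid markers passed without wild type DN4 replicate 3 (adjusted p = 0.0371) or Lmo2tg DN4 replicate 3 (0.0302) or 4 (0.0358). NK markers did without Lmo2tg DN4 replicate 2 (adjusted p = 0.0482), 3 (0.0444) or 4 (0.0226). The other 7 lists had adjusted p from 0.0853 to 0.945.

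Ldb1-KO against Lmo2tg at DN2/3 asks what deleting Ldb1 changes. Hoxa7, Mira, Kazn and Cdkn1a rose, and Ryr2, Slc22a4 and Pof1b fell. Hoxa7 went from 0.0488 ± 0.0581 CPM to 8.26 ± 3.52 CPM in 5 Ldb1-KO libraries (log2 fold 7.49, SE 0.63, adjusted p = 7.24e-09). Ryr2 went from 20.2 ± 12.7 to 0.264 ± 0.345 CPM (log2 fold -6.53, SE 0.89, adjusted p = 2.39e-05). In all, 2312 genes changed, 1275 higher and 1037 lower in Ldb1-KO, of which 872 and 415 by over 2-fold. Of 25 stem and progenitor regulators 14 rose and 0 fell (16 rose adjusted over the list alone, adjusted p = 8.39e-11, estimated 0.0192). This was the only list whose call held with an estimated correlation.

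Kazn rose to 7.65 ± 4.24 against 0.011 ± 0.0151 CPM (log2 fold 8.90, SE 0.70, adjusted p = 3.16e-09). Mira rose to 9.11 ± 3.05 against 0.0202 ± 0.0451 CPM (log2 fold 8.43, SE 0.68, adjusted p = 3.28e-09). Ifi44 rose to 8.95 ± 3.37 against 0.0384 ± 0.0529 CPM (log2 fold 7.52, SE 0.85, adjusted p = 4.68e-07). The circadian regulator gene Npas2 rose to 5.86 ± 3.37 against 0.0529 ± 0.0752 CPM (log2 fold 6.94, SE 0.75, adjusted p = 2.37e-07). The progesterone receptor gene Pgr rose to 7.34 ± 12.9 against 0.0115 ± 0.0258 CPM (log2 fold 8.83, SE 1.63, adjusted p = 0.000481), with replicate 5 at 30.1 CPM and the other Ldb1-KO libraries from 0.325 to 5.24.

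Slc22a4 fell to 0.386 ± 0.252 against 28.5 ± 5.55 CPM (log2 fold -6.23, SE 0.60, adjusted p = 1.3e-07). Pof1b fell to 0.0446 ± 0.0637 against 31.3 ± 34.7 CPM (log2 fold -9.61, SE 1.74, adjusted p = 0.000337). Tmem45a fell to 0.0446 ± 0.0637 against 5.32 ± 3.18 CPM (log2 fold -7.02, SE 0.82, adjusted p = 7.62e-07). The zinc finger gene Plagl1 fell to 0.219 ± 0.122 against 12 ± 8.27 CPM (log2 fold -5.80, SE 0.57, adjusted p = 6.23e-08). Faxc fell to 0.267 ± 0.508 against 12.9 ± 4.75 CPM (log2 fold -5.74, SE 1.06, adjusted p = 0.000419).

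Among the lists at DN2/3, Cdkn1a rose in Ldb1-KO to 30.6 ± 8.4 against 2.77 ± 1.64 CPM (log2 fold 3.47, SE 0.40, adjusted p = 6.01e-07). Interferon response genes had 6 rises among 20 (10 adjusted over the list alone, adjusted p = 0.000232, estimated 0.824). Oasl2 rose to 23.9 ± 8 against 5.35 ± 2.55 CPM (log2 fold 2.15, adjusted p = 0.00295). Cytokine receptors had 6 rises and 1 fall (adjusted p = 0.0444, estimated 0.824). Csf2ra rose to 22.2 ± 4.83 against 3.72 ± 3.32 CPM (log2 fold 2.59, adjusted p = 0.000162). Il17rb rose to 258 ± 48.9 against 142 ± 33.8 CPM (log2 fold 0.86, adjusted p = 0.00162). Glycolysis genes had 3 falls (adjusted p = 0.0243, estimated 0.824). The hexokinase gene Hk1 fell to 162 ± 26.5 against 248 ± 48.2 CPM (log2 fold -0.61, adjusted p = 0.00258). Pfkp fell to 49.5 ± 7.19 against 85 ± 22.6 CPM (log2 fold -0.78, adjusted p = 0.00294). Thymic stroma markers had 2 rises among 7 (adjusted p = 0.0243, estimated 0.127). The stroma call ended without Ldb1-KO DN2/3 replicate 1 (adjusted p = 0.0597). That on cytokine receptors ended without Lmo2tg DN2/3 replicate 2 (0.0525), 3 (0.0714) or 4 (0.126) or Ldb1-KO DN2/3 replicate 1 (0.0743). That on glycolysis ended without Lmo2tg DN2/3 replicate 2 (0.0781) or 4 (0.0574) or Ldb1-KO DN2/3 replicate 1 (0.0597).

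In the remaining lists at DN2/3, the T-lineage gene Cd3g rose in Ldb1-KO to 862 ± 120 against 491 ± 65.8 CPM (log2 fold 0.81, adjusted p = 6.92e-06). Ptcra rose to 96.1 ± 33.5 against 31.7 ± 8.98 CPM (log2 fold 1.60, adjusted p = 0.000107). The Notch target Trib2 fell to 42.8 ± 8.36 against 90.8 ± 26.8 CPM (log2 fold -1.09, adjusted p = 0.000427). The survival gene Bcl2 rose to 203 ± 29.9 against 93.3 ± 15.1 CPM (log2 fold 1.12, adjusted p = 0.001). Bbc3 fell to 8.88 ± 3.51 against 20.8 ± 5.85 CPM (log2 fold -1.23, adjusted p = 0.00258). The inhibitor Cdkn1c fell to 0.713 ± 0.205 against 2.02 ± 0.528 CPM (log2 fold -1.49, adjusted p = 0.000215). The partner Tcf4 rose to 66.4 ± 10.6 against 37.6 ± 5.83 CPM (log2 fold 0.82, adjusted p = 0.000811). No cell cycle gene passed, and Mki67, a proliferation marker, had 682 ± 143 against 709 ± 270 CPM (adjusted p = 0.884). The cell cycle list did not pass (adjusted p = 0.608) but did, lower, without Lmo2tg DN2/3 replicate 1 (0.036). Myeloid markers (adjusted p = 0.0694) passed, higher, without Lmo2tg DN2/3 replicate 2 (0.0137) and immediate early genes (0.0853) without Lmo2tg DN2/3 replicate 4 (0.0406) or Ldb1-KO DN2/3 replicate 2 (0.0234) or 3 (0.0265). Bop1 fell to 128 ± 16.5 against 201 ± 37.7 CPM (log2 fold -0.66, adjusted p = 0.0311). That call ended without Lmo2tg DN2/3 replicate 2 (adjusted p = 0.0818) or 4 (0.0786) or Ldb1-KO DN2/3 replicate 1 (0.066), 2 (0.0742), 3 (0.0618) or 5 (0.0678).

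**Figure D2:**
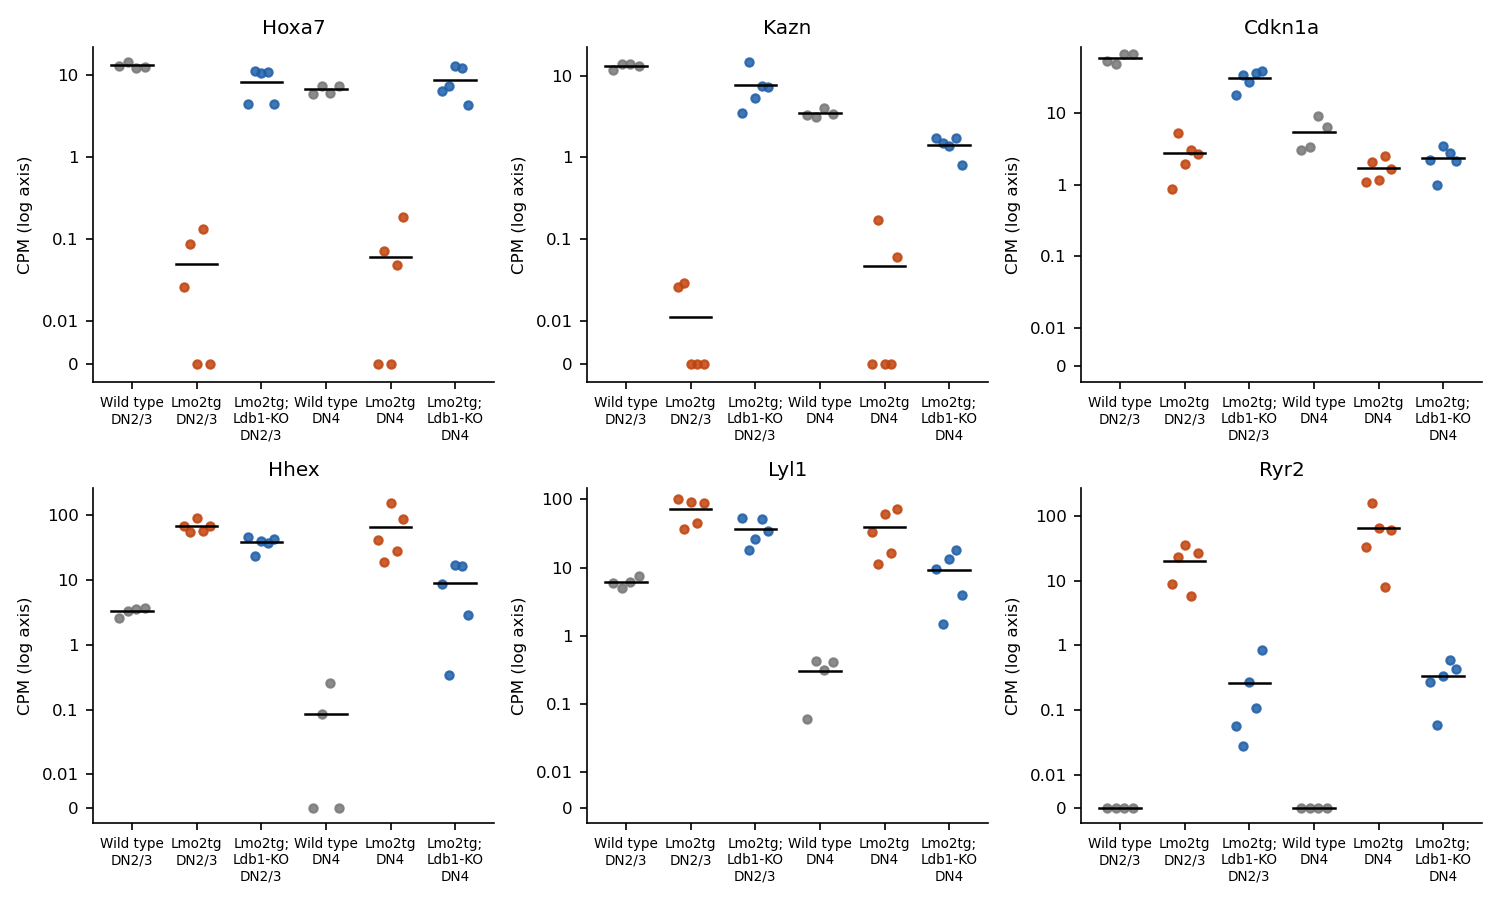
CPM of Hoxa7, Kazn, Cdkn1a, Hhex, Lyl1 and Ryr2 in each library of the 6 groups, on a log axis with libraries at 0 drawn at the bottom and a line at the group mean.

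At DN4, Hoxa7 and Mira rose in Ldb1-KO over Lmo2tg, while Ryr2, Slc22a4 and Kit fell. Of 33 cell cycle genes 11 rose (18 adjusted over the list alone, adjusted p = 3.77e-10, estimated 0.794) and of 12 B cell markers 7 fell (adjusted p = 0.0057, estimated 0.794), and neither call held when estimated. The B cell call ended without Lmo2tg DN4 replicate 1 (adjusted p = 0.0556). Hoxa7 went from 0.0599 ± 0.0748 to 8.59 ± 3.75 CPM (log2 fold 7.31, SE 0.63, adjusted p = 2.08e-08). Ryr2 went from 65.8 ± 57.1 to 0.337 ± 0.196 CPM (log2 fold -7.72, SE 0.90, adjusted p = 9e-06), in 5 libraries each. In all, 2092 genes changed, 841 higher and 1251 lower in Ldb1-KO, of which 372 and 650 by over 2-fold. A model of the compared groups only gave 681 genes, and the cause was not tested.

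Mira rose to 11.2 ± 5.17 against 0.0193 ± 0.0432 CPM (log2 fold 8.73, SE 0.69, adjusted p = 8.98e-09). Pla2g4a rose to 6.93 ± 1.65 against 0.193 ± 0.181 CPM (log2 fold 5.15, SE 0.54, adjusted p = 3.34e-07). The DNA sensor gene Aim2 rose to 24.4 ± 6 against 1.18 ± 1.3 CPM (log2 fold 4.32, SE 0.59, adjusted p = 1.4e-05). Zfp518b rose to 6.69 ± 1.37 against 0.397 ± 0.462 CPM (log2 fold 4.01, SE 0.45, adjusted p = 9.95e-07). Eci1, an enzyme of fatty acid oxidation, rose to 5.65 ± 2.49 against 0.454 ± 0.373 CPM (log2 fold 3.61, SE 0.44, adjusted p = 3.87e-06).

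Pof1b fell to 0.0463 ± 0.0737 against 50.3 ± 74.1 CPM (log2 fold -9.97, SE 1.72, adjusted p = 0.000379). Slc22a4 fell to 0.0901 ± 0.0633 against 7.91 ± 5.7 CPM (log2 fold -6.54, SE 0.67, adjusted p = 5.73e-07). Faxc fell to 0.137 ± 0.252 against 8.74 ± 5.01 CPM (log2 fold -6.25, SE 1.12, adjusted p = 0.000559). The ephrin receptor gene Ephb4 fell to 0.537 ± 0.706 against 21.8 ± 15 CPM (log2 fold -5.26, SE 0.84, adjusted p = 0.000119). Chst1 fell to 0.0593 ± 0.0445 against 6.89 ± 14 CPM (log2 fold -6.72, SE 1.58, adjusted p = 0.00452). This rested on Lmo2tg DN4 replicate 5 at 31.9 CPM, without which the log2 fold change was -3.34 (adjusted p = 0.0776).

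In Ldb1-KO DN4 the cell cycle gene Rrm2, which serves nucleotide synthesis, rose to 724 ± 41.4 against 387 ± 124 CPM (log2 fold 0.90, SE 0.20, adjusted p = 0.00254). Tyms rose to 197 ± 7.67 against 109 ± 38.3 CPM (log2 fold 0.86, SE 0.20, adjusted p = 0.00438). Stem and progenitor regulators had 6 rises and 9 falls (adjusted p = 0.906). Hoxa9 rose to 3.45 ± 2.86 against 0.0327 ± 0.0557 CPM (log2 fold 6.39, SE 0.91, adjusted p = 2.53e-05). Cytokine receptors had 3 rises and 4 falls (adjusted p = 0.314). The interleukin-7 receptor gene Il7r fell to 30.4 ± 9.5 against 108 ± 71.5 CPM (log2 fold -1.82, adjusted p = 0.000681). Kit fell to 40.2 ± 14.6 against 113 ± 68.2 CPM (log2 fold -1.49, adjusted p = 0.000903).

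The T-lineage gene Thy1 rose to 1730 ± 100 against 1040 ± 281 CPM (log2 fold 0.73, adjusted p = 0.000234). The Ets factor gene Spib fell to 3.82 ± 1.59 against 10.6 ± 4.18 CPM (log2 fold -1.48, adjusted p = 0.00233). The Notch target Heyl fell to 2.32 ± 0.59 against 5.6 ± 1.89 CPM (log2 fold -1.27, adjusted p = 0.00076). Trib2 fell to 76.5 ± 6.76 against 145 ± 56.5 CPM (log2 fold -0.92, adjusted p = 0.00306), a call that ended in a model of the compared groups only (0.051).

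The Ldb1 partner gene Ssbp2 rose at DN4 to 82.2 ± 15.8 against 48.3 ± 11.9 CPM (log2 fold 0.77, adjusted p = 0.000317). The inhibitor Cdkn1c fell to 1.8 ± 0.609 against 3.8 ± 0.507 CPM (log2 fold -1.07, adjusted p = 0.00561). Cdkn2a fell to 0.682 ± 0.717 against 6.36 ± 4.16 CPM (log2 fold -3.21, adjusted p = 0.00658). Bbc3 fell to 7.53 ± 1.56 against 21.5 ± 8.65 CPM (log2 fold -1.51, adjusted p = 0.000582). The glucose transporter gene Slc2a3 fell to 34 ± 3.01 against 49 ± 10.9 CPM (log2 fold -0.53, adjusted p = 0.0102). Hk1 fell to 119 ± 14.8 against 170 ± 34.4 CPM (log2 fold -0.51, adjusted p = 0.0127). Interferon genes did not pass as a list (adjusted p = 0.0994) but did without Lmo2tg DN4 replicate 1 (2.31e-05) or 3 (0.0396) or Ldb1-KO DN4 replicate 4 (0.0471). Ifi44 rose to 1.71 ± 0.696 against 0.126 ± 0.22 CPM (log2 fold 3.59, adjusted p = 0.00106). Oas1a rose to 6.67 ± 2.7 against 2.06 ± 1.51 CPM (log2 fold 1.70, adjusted p = 0.0226). No change passed in Npm1, a nucleolar protein gene (1920 ± 236 against 1760 ± 636 CPM, adjusted p = 0.759). The call on Hk1 ended without Lmo2tg DN4 replicate 5 (adjusted p = 0.0529) and that on Oas1a without Lmo2tg DN4 replicate 2 (0.0527) or Ldb1-KO DN4 replicate 3 (0.0663). A model of the compared groups only ended the calls on Cdkn2a (0.0546), Slc2a3 (0.0761), Hk1 (0.078) and Oas1a (0.14).

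Genes changed by the transgene often changed the opposite way when Ldb1 was deleted. At DN2/3, 1800 of the 4242 genes (42.4%) did so: 786 rose and then fell, where 156.9 would be shared by independent calls, and 1014 fell and then rose (183.4 by independent calls). Among these were 12 of 25 stem and progenitor regulators, each lower in Lmo2tg and higher in Ldb1-KO, including Hoxa7, Hoxa9, Cd34, Meis1 and Mef2c, the last 3 named after their values were seen. At DN4 it was 1736 of 7532 genes (23.05%), 1068 higher then lower (361.1 by independent calls) and 668 lower then higher (198). These included Hhex, Lyl1, Kit and 7 B cell markers, higher then lower, and 10 cell cycle genes, lower then higher. The shared Lmo2tg libraries alone give a negative correlation, and no list was recounted with them split. Across genes, which are not independent replicates, the log2 fold changes had r = -0.774 and a covariance of -1.224 at DN2/3. At DN4 these were -0.71 and -1.08. Simulated unchanged groups gave r = -0.474 and -0.473 and covariances of -0.073 and -0.072. With shared libraries 7 genes rose and 3 fell in both comparisons at DN2/3, and 6 and 3 at DN4. With different Lmo2tg libraries in each comparison these were 16 and 18 at DN2/3 and 117 and 116 at DN4. The opposite shares were then 25.1% (1069 of 4267, r = -0.56) and 9.47% (781 of 8249, r = -0.306). At DN2/3, 476 rose then fell (119.5 by independent calls) and 593 fell then rose (122.6), and at DN4 544 (317.2) and 237 (155.4).

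**Figure D3:**
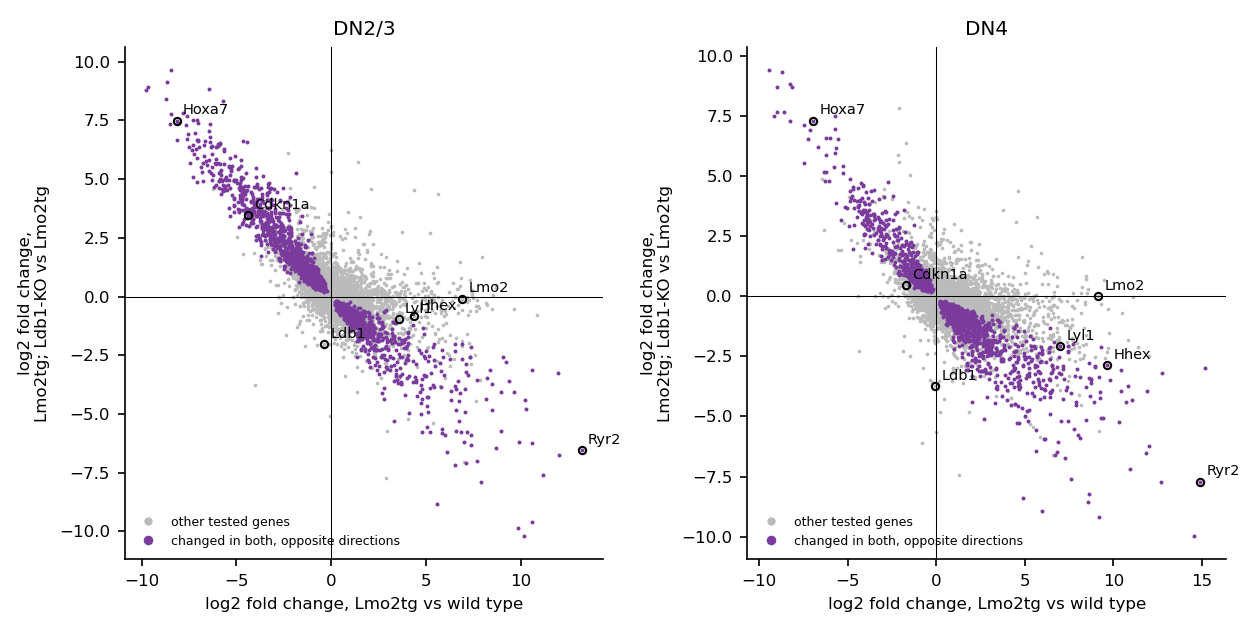
Log2 fold change of every tested gene in Ldb1-KO against Lmo2tg (vertical) plotted against that in Lmo2tg against wild type (horizontal), at DN2/3 and DN4, with genes changed in both in opposite directions in purple.

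Ldb1-KO against wild type joins transgene and Ldb1 deletion, which it cannot part, with 19.2% (DN2/3) and 7.16% (DN4) of the wild-type Ldb1 level left. At DN2/3, Lmo2 rose (log2 fold 6.82, SE 0.34, adjusted p = 4.35e-14). Ldb1 fell (log2 fold -2.38, SE 0.35, adjusted p = 4.46e-05). Rises passed in 8 of 13 myeloid markers (adjusted p = 6.07e-05, estimated 0.0949) and 9 of 15 immediate early genes (adjusted p = 2.3e-06, estimated 0.224), and neither call held when estimated. Of 14371 genes, 1374 changed, 1003 higher and 371 lower in Ldb1-KO. At DN4, Lmo2 rose (log2 fold 9.14, SE 0.40, adjusted p = 2.41e-15), with 4680 genes changed, 2615 higher and 2065 lower. Of 20 interferon response genes 15 rose (adjusted p = 0.000164, estimated 0.372) and of 21 ribosome biogenesis genes 16 fell (adjusted p = 5.85e-07, estimated 0.372), and neither call held when estimated. The DN2/3 count was 764, 877 and 880 without wild type DN2/3 replicate 1, 3 and 4, 863 without Ldb1-KO DN2/3 replicate 3, and 3037 in a model of the compared groups only, and the DN4 count was 2855 without wild type DN4 replicate 3.

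At DN2/3, cell cycle inhibitors had 6 rises among 14 (adjusted p = 0.00137, estimated 0.0949). Stem and progenitor regulators had 5 rises among 25 (adjusted p = 0.00442, estimated 0.301). Mature T markers had 5 rises among 12 (adjusted p = 0.00137, estimated 0.224). NK markers had 3 rises (adjusted p = 0.0182, estimated 0.313). Complex genes had 3 rises, 1 of them Lmo2, and a fall in Ldb1 alone (adjusted p = 0.0339, estimated 0.224), and the list did not pass without these (0.516).

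At DN4, cell cycle inhibitors had 10 rises and 1 fall (adjusted p = 0.00023, estimated 0.0378), a call that held. Stem and progenitor regulators had 12 rises and 1 fall (adjusted p = 0.00254, estimated 0.372). T-lineage genes had 9 rises and 1 fall (adjusted p = 0.0218, estimated 0.372). Cytokine receptors had 9 rises (adjusted p = 0.0407, estimated 0.372). Glycolysis genes had 1 rise and 7 falls (adjusted p = 0.0192, estimated 0.411). B cell markers had 5 rises (adjusted p = 0.0328, estimated 0.372). Mature T markers had 8 rises (adjusted p = 0.000168, estimated 0.316). Immediate early genes had 12 rises (adjusted p = 3.2e-05, estimated 0.372). The cell cycle list was lower (adjusted p = 0.0306, estimated 0.635) with 0 single genes passing. The call on cytokine receptors ended without wild type DN4 replicate 1 (adjusted p = 0.0522) or 4 (0.0549) or Ldb1-KO DN4 replicate 4 (0.0512). That on B cell markers ended without Ldb1-KO DN4 replicate 4 (0.0838).

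Srp54b, Mir684-1 and Entpd4 rose most in Ldb1-KO DN2/3. Srp54b, a signal recognition particle gene, had 34.7 ± 1.15 against 0.107 ± 0.176 CPM (log2 fold 8.58, SE 0.46, adjusted p = 2.11e-13). Mir684-1 rose to 30.6 ± 10.3 against 0.153 ± 0.0732 CPM (log2 fold 7.58, SE 0.52, adjusted p = 3.21e-11). Entpd4, a nucleotide-hydrolysing enzyme gene, had 62.5 ± 2.61 against 0.485 ± 0.545 CPM (log2 fold 7.13, SE 0.48, adjusted p = 3.06e-11). Srp54b and Entpd4 share 88% and 100% of their 101-base stretches with other genes, so their values against wild type are uncertain. Tmem180 fell to 10.7 ± 2.23 against 68.9 ± 7.78 CPM (log2 fold -2.68, SE 0.78, adjusted p = 0.0276). Alpl, the tissue-nonspecific alkaline phosphatase gene, fell to 1.02 ± 0.477 against 6.34 ± 0.902 CPM (log2 fold -2.65, SE 0.77, adjusted p = 0.0277). Tmem180's call ended without wild type DN2/3 replicate 1, 2, 3 or 4 or Ldb1-KO replicate 1, 3 or 5 (adjusted p 0.0509 to 0.0767). That of Alpl ended without wild type DN2/3 replicate 1, 3 or 4 or Ldb1-KO replicate 1, 3 or 5 (0.0537 to 0.08).

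At DN4 the C-type lectin gene Clec4e rose to 10.3 ± 8.44 against 0.0127 ± 0.0254 CPM (log2 fold 9.30, SE 1.39, adjusted p = 4.06e-05). The metalloprotease gene Adam12 rose to 8.08 ± 8.86 against 0.0127 ± 0.0254 CPM (log2 fold 8.98, SE 1.44, adjusted p = 0.000144). Ldb1 fell (log2 fold -3.81, SE 0.37, adjusted p = 4.56e-08). Tmem180 fell to 2.84 ± 0.849 against 31.8 ± 1.59 CPM (log2 fold -3.48, SE 0.81, adjusted p = 0.00309). Lmo2tg replicates 1 and 2 had 0.55 and 0.92 CPM (DN2/3 1.7 and 1.11), the others at least 9.04. Adam11 fell to 1.37 ± 0.557 against 9.09 ± 4.79 CPM (log2 fold -2.73, SE 0.58, adjusted p = 0.00163).

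**Figure D4:**
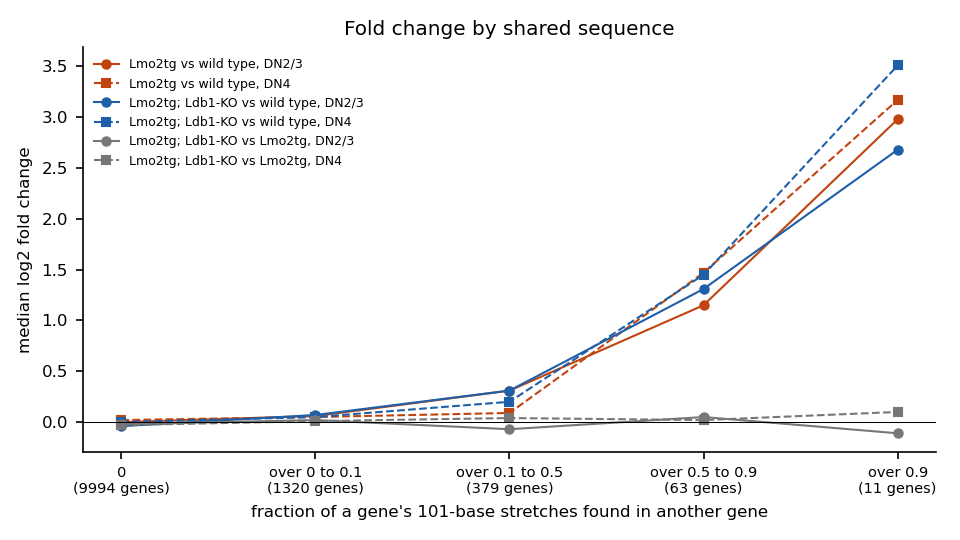
Median log2 fold change (vertical) of genes grouped by the share of their 101-base stretches that occur in another gene (horizontal, 9994, 1320, 379, 63 and 11 genes per group) in 6 comparisons between genotypes.

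The comparison of DN4 with DN2/3 in each genotype asks how the stages differ. In wild type, the CD8 gene Cd8a rose to 33.6 ± 16.5 against 0.718 ± 0.364 CPM over 4 libraries per stage (log2 fold 5.56, SE 0.60, adjusted p = 2.07e-07). Cd8b1 rose to 120 ± 26.6 against 2.81 ± 0.882 CPM (log2 fold 5.42, SE 0.43, adjusted p = 1.43e-09). Pdlim4 rose to 5.96 ± 2.21 against 0.178 ± 0.0893 CPM (log2 fold 5.01, SE 0.63, adjusted p = 1.37e-06). The lysozyme gene Lyz2 fell to 0.0714 ± 0.0556 against 16.4 ± 3.3 CPM (log2 fold -7.80, SE 0.83, adjusted p = 1.52e-07). Ctla2a fell to 0.585 ± 0.291 against 70.4 ± 11.2 CPM (log2 fold -6.90, SE 1.05, adjusted p = 1.55e-05). The Ets factor gene Erg fell to 0.435 ± 0.18 against 46.7 ± 2.1 CPM (log2 fold -6.75, SE 0.92, adjusted p = 4.39e-06). Lmo2 fell (log2 fold -1.75, adjusted p = 0.00243) and Ldb1 did not pass (adjusted p = 0.259), but did in a model of the compared groups only (0.000162). In all 6606 genes changed, 3035 higher and 3571 lower.

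All 33 cell cycle genes rose in wild type DN4 (adjusted p = 1.39e-17, estimated 0.346). Of 21 ribosome biogenesis genes 18 rose (adjusted p = 2.9e-05, estimated 0.54). Of 17 glycolysis genes 11 rose (adjusted p = 0.000608, estimated 0.447). Falls took in 16 of 25 stem regulators (adjusted p = 1.3e-06, estimated 0.0724). Notch targets had 9 falls (adjusted p = 2.9e-05, estimated 0.0724). Interferon genes had 16 falls (adjusted p = 0.00115, estimated 0.55). Cytokine receptors had 12 falls (adjusted p = 0.0233, estimated 0.489). Stroma markers had 4 falls (adjusted p = 0.0126, estimated 0.0724). Immediate early genes had 10 falls (adjusted p = 0.0221, estimated 0.55), a call that ended without wild type DN2/3 replicate 3 (0.0665). Myeloid markers had 5 falls (adjusted p = 0.0307, estimated 0.436, and adjusted p = 0.186 with pairs as a block).

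In Lmo2tg, the ion channel gene Trpm1 rose from DN2/3 to DN4, to 17.7 ± 17.3 against 0.179 ± 0.165 CPM (log2 fold 6.51, SE 0.81, adjusted p = 9.46e-06). The inhibitory receptor gene Btla rose to 38.4 ± 35.5 against 0.461 ± 0.329 CPM (log2 fold 6.30, SE 0.71, adjusted p = 3.77e-06). Arhgap20 rose to 7.65 ± 7.98 against 0.107 ± 0.111 CPM (log2 fold 6.14, SE 0.76, adjusted p = 9.46e-06). The interleukin-2 receptor gene Il2ra fell to 71.1 ± 36.4 against 779 ± 159 CPM (log2 fold -3.45, SE 0.30, adjusted p = 1.88e-07). Drc7 fell to 1.1 ± 0.414 against 11.4 ± 6.98 CPM (log2 fold -3.38, SE 0.65, adjusted p = 0.000838). Mpzl2 fell to 34.3 ± 16.6 against 222 ± 71.1 CPM (log2 fold -2.70, SE 0.30, adjusted p = 3.58e-06). Lmo2 and Ldb1 did not pass (adjusted p = 0.172 and 0.721). In all 2208 genes changed, 1196 higher and 1012 lower. With pairs as a block the count was 5569, in a model of these groups only 321, and without Lmo2tg DN4 replicate 4 it was 3450.

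In Lmo2tg DN4, Notch targets had 6 falls among 12 (adjusted p = 5.33e-06, estimated 0.102). Cell cycle genes had 3 rises among 33 (adjusted p = 0.0317, estimated 0.876). Cell cycle inhibitors had 6 rises (adjusted p = 0.00634, estimated 0.108). NK markers had 8 rises (adjusted p = 0.000145, estimated 0.108). B cell markers had 7 rises (adjusted p = 0.00454, estimated 0.353). Dendritic markers had 4 rises (adjusted p = 0.00371, estimated 0.217). Gamma-delta T markers had 3 rises (adjusted p = 0.0039, estimated 0.108). Mature T markers had 6 rises (adjusted p = 0.00371, estimated 0.257). Myeloid markers had 7 falls (adjusted p = 0.0134, estimated 0.257). Complex genes did not pass (adjusted p = 0.0539) but did, lower, without Lmo2 and Ldb1 in the list (0.0223), with RLE normalization (0.0481) and without Lmo2tg DN2/3 replicate 4 (0.0422) or Lmo2tg DN4 replicate 3 (0.0296) or 5 (0.0453). The cell cycle call ended without Lmo2tg DN2/3 replicate 1 (adjusted p = 0.507), 3 (0.0781) or 5 (0.155) or Lmo2tg DN4 replicate 2 (0.186) or 4 (0.873). That on B cell markers ended without Lmo2tg DN2/3 replicate 2 (0.0565) or Lmo2tg DN4 replicate 5 (0.05). That on myeloid markers ended without Lmo2tg DN2/3 replicate 2 (0.109) or Lmo2tg DN4 replicate 4 (0.0941).

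In Ldb1-KO, Trpm1 rose from DN2/3 to DN4, to 15.7 ± 8.52 against 0.232 ± 0.0898 CPM (log2 fold 6.11, SE 0.80, adjusted p = 4.09e-06). Lysmd2 rose to 5.23 ± 2.91 against 0.124 ± 0.0919 CPM (log2 fold 5.29, SE 0.79, adjusted p = 2.05e-05). Adam12 rose to 8.08 ± 8.86 against 0.202 ± 0.235 CPM (log2 fold 5.23, SE 1.02, adjusted p = 0.00055). Pgr fell to 0.0254 ± 0.0349 against 7.34 ± 12.9 CPM (log2 fold -8.54, SE 1.63, adjusted p = 5e-04). The progenitor marker gene Cd34 fell to 0.0503 ± 0.0949 against 9.34 ± 1.43 CPM (log2 fold -7.81, SE 0.99, adjusted p = 5.47e-06). The actin-severing protein gene Scin fell to 1.82 ± 0.761 against 275 ± 122 CPM (log2 fold -7.20, SE 0.57, adjusted p = 4.32e-09). Ldb1 fell (log2 fold -1.94, SE 0.34, adjusted p = 0.000146). Lmo2 did not pass (log2 fold 0.57, SE 0.23, adjusted p = 0.0615) but did with pairs as a block (0.59, adjusted p = 0.00861), in a model of these groups only (0.00992), by DESeq2 (0.0188), without Ldb1-KO DN2/3 replicate 1 (0.0286) and without Ldb1-KO DN4 replicate 4 (0.0497). In all 4039 genes changed, 1765 higher and 2274 lower, and 6934 with pairs as a block.

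Of 25 stem and progenitor regulators 17 fell from DN2/3 to DN4 in Ldb1-KO (adjusted p = 1.59e-09, estimated 0.024). Notch targets had 8 falls among 12 (adjusted p = 1.16e-07, estimated 0.024). Myeloid markers had 10 falls among 13 (adjusted p = 7.77e-07, estimated 0.024). Megakaryocyte markers had 4 falls among 4 (adjusted p = 0.00256, estimated 0.024). Stroma markers had 4 falls among 7 (adjusted p = 0.00459, estimated 0.024). These calls held. Cell cycle genes had 26 rises among 33 (adjusted p = 2.06e-15, estimated 0.271). Complex genes had 10 falls and 3 rises among 18 (adjusted p = 0.0105, estimated 0.0612, and 0.0124 without Lmo2 and Ldb1). Cytokine receptors had 11 falls and 3 rises (adjusted p = 0.0105, estimated 0.432). Immediate early genes had 8 falls (adjusted p = 0.00367, estimated 0.479).

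**Figure D5:**
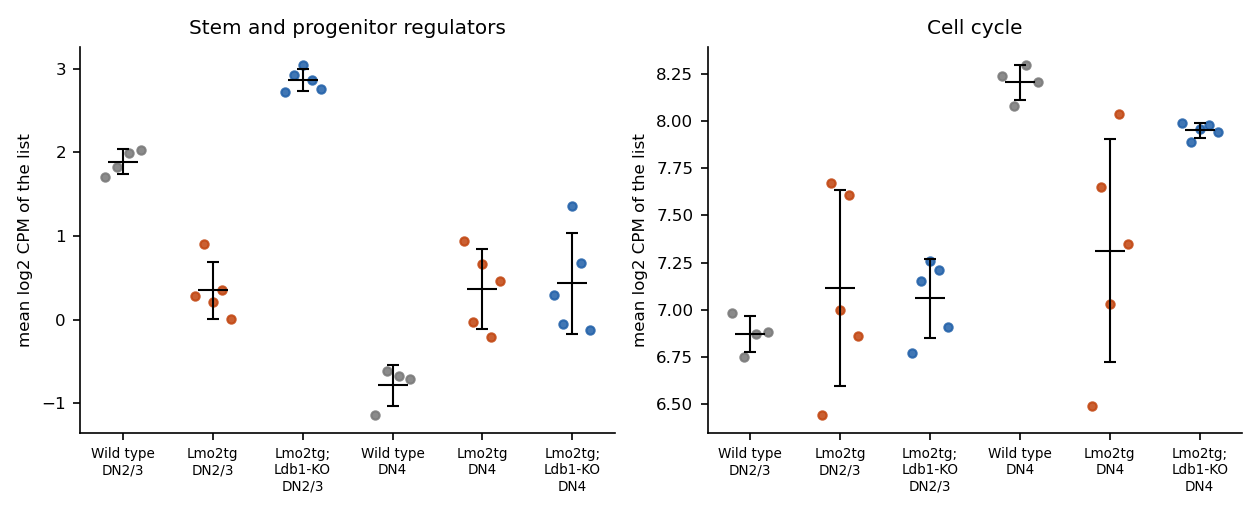
Mean log2 CPM of the stem and progenitor regulators and of the cell cycle genes in each library of the 6 groups, with the group mean ± SD.

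The effect of the transgene differed between the stages for 3684 genes, 2106 with a more positive and 1578 with a more negative effect at DN4 (7106 with pairs as a block, 2146 in a model of these groups only, 2412 without wild type DN2/3 replicate 2). The difference was positive in Npas2 (log2 fold 7.78, SE 0.99, adjusted p = 2.24e-05). It was also positive in Ubqlnl (adjusted p = 0.00781), whose fitted size rests on wild type DN4 at 0 counts. The difference was negative in the sulfatase gene Arsi (log2 fold -3.62, SE 0.68, adjusted p = 0.000907). Pdlim4 had a negative difference as well (log2 fold -3.37, SE 0.74, adjusted p = 0.00319). The class I histocompatibility gene H2-Q1 did too (log2 fold -3.11, SE 0.39, adjusted p = 1.93e-05).

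The effect was more positive at DN4 in 17 of 25 stem regulators (adjusted p = 7.12e-09, estimated 0.0545). Interferon genes had 13 positive differences among 20 (adjusted p = 2.96e-05, estimated 0.294). Cytokine receptors had 6 (adjusted p = 0.00369, estimated 0.294). T-lineage genes had 7 positive and 2 negative (adjusted p = 0.0432, estimated 0.294). Notch targets had 5 positive and 1 negative (adjusted p = 0.0467, estimated 0.294, and adjusted p = 0.0544 with pairs as a block). The effect was more negative in 27 of 33 cell cycle genes (adjusted p = 1.11e-14, estimated 0.294). Ribosome biogenesis genes had 9 negative differences among 21 (adjusted p = 1.66e-07, estimated 0.294). Glycolysis genes had 5 negative and 1 positive (adjusted p = 0.000186, estimated 0.294). The call on T-lineage genes ended without wild type DN2/3 replicate 1 (adjusted p = 0.0675), wild type DN4 replicate 2 (0.0519) or 4 (0.0712), Lmo2tg DN2/3 replicate 4 (0.0634) or Lmo2tg DN4 replicate 1 (0.0542) or 2 (0.0546). That on Notch targets ended without wild type DN2/3 replicate 1 (0.0767) or 3 (0.0551), wild type DN4 replicate 1 (0.0529), 2 (0.0519) or 4 (0.0712), Lmo2tg DN2/3 replicate 1 (0.0533), 3 (0.0568) or 5 (0.0906) or Lmo2tg DN4 replicate 2 (0.0929) or 4 (0.205).

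The effect of deleting Ldb1 differed between the stages for 195 genes, 19 with a more positive and 176 with a more negative effect at DN4 (with pairs as a block 1933, 898 positive and 1035 negative, a slight lean, 389 with DESeq2, 85 in a model of these groups only, 624 without Lmo2tg DN4 replicate 4). The difference was positive in Arhgap19 (log2 fold 1.55, SE 0.19, adjusted p = 4.63e-05). The cell cycle repressor gene E2f7 had a positive difference (log2 fold 1.36, SE 0.29, adjusted p = 0.0107), as did the cyclin gene Ccnd3 (log2 fold 1.08, SE 0.25, adjusted p = 0.024). The imprinted noncoding RNA H19 had a negative difference (log2 fold -6.51, SE 1.02, adjusted p = 0.000827). So did the B cell kinase gene Btk (log2 fold -6.26, SE 0.81, adjusted p = 9.79e-05). Scin did too (log2 fold -5.96, SE 0.67, adjusted p = 3.27e-05). The call on Ccnd3 ended in a model of these groups only (adjusted p = 0.0977) and without Lmo2tg DN2/3 replicate 4, Ldb1-KO DN2/3 replicate 1 or 2, or Ldb1-KO DN4 replicate 4 or 5 (0.0513 to 0.0561). Stem and progenitor regulators had a more negative effect at DN4 (8 of 25, 15 adjusted over the list alone, adjusted p = 4.32e-18, estimated 0.000782). That call held, as did that on thymic stroma markers (adjusted p = 0.000568, estimated 0.0154). The cell cycle list was more positive (adjusted p = 3.6e-16, estimated 0.226) with 0 single genes passing.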

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

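The tests of a strain or copy number difference and of B cells in the sort were chosen after the result had been seen.

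In all, 70 genes were over 8-fold lower in the wild-type libraries than in both transgenic genotypes at both stages, with under 2-fold between the transgenic genotypes. Of the 65 with a value for shared sequence, 38 (58.5%) share at least 10% of their 101-base stretches with a gene elsewhere, against 529 of the tested genes (3.9%). The 11 genes with at least 90% shared rose over wild type in all 4 comparisons with it, and the smaller of the stage differences in median log2 fold change, Ldb1-KO against wild type, between shared and unshared genes was 2.72, above the bound of 1 set for reads of near-identical copies being counted in the transgenic libraries and not in wild type. Another 18 of the genes have no shared stretch, Lmo2, which the transgene itself supplies, among them. A strain or copy number difference may add to the pattern in others, and neither it nor an effect of the transgene can be told apart from a difference between library series, since genotype and series are the same split. Srp54b and Entpd4 are examples.

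B cell transcripts were highest in Lmo2tg DN4 replicate 1, with Ms4a1 at 17.6 and Cd74 at 104 CPM, against wild type DN4 means of 0.00634 and 0.62 CPM. A candidate explanation is B cells in the sorted population, which the DN gate should remove. Of 12 further B cell genes, 7 were highest there of the 10 transgenic DN4 libraries. With bounds of at least 9 and at most 4 set for and against it, B cells cannot be told apart from thymocyte expression. The 7 had 0 to 1.04 CPM in wild type DN4, the others 1.5 to 99.9. Expression of these genes by the thymocytes themselves was not tested.

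In Ldb1-KO DN4, genes raised by the transgene stayed partly above wild type. Over 452 genes raised at least 4-fold in Lmo2tg, a median of 34.2% of the rise was left (quartiles 16.5 and 59.4), against 7.43% of the Ldb1 level. Cells that kept Ldb1 could leave part of it, but the share left was over 3 times that of Ldb1 in 4 of 5 libraries and 1.85 times in replicate 4, short of the bound of all 5 set against this. A library series difference may also hold levels up, the lowest library having 23.2% left (replicate 2, with 1.77% of Ldb1), and it cannot be told apart from genotype. At DN2/3 the median over 210 genes chosen likewise was 18.8% against 24.7% of Ldb1, and a rise that does not need Ldb1 stays open and untested.

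Single libraries stood apart from the others of their group in 31 of 369 groups. Chance gives about 1 in 20, but with the others all at 0 a few counts force the call, so that rate is no yardstick there. In Lmo2tg DN4 replicate 1 these included Lmo2 (68.9 CPM, the others 36.1 to 41.9), Mira (0.0965 CPM, the others 0), Aim2 (3.43 CPM, 0.0479 to 0.98), Zfp518b (1.22 CPM, 0.178 to 0.209), Hoxa9 (0.129 CPM, 0 to 0.0348) and Ifi44 (0.515 CPM, 0 to 0.0696). In Lmo2tg DN4 replicate 2 they included Msantd3 (0.0348 CPM, the others 0) and Slc16a3 (19.2 CPM, 4.19 to 7.04). In Lmo2tg DN4 replicate 5 they were Thsd4 (65.5 CPM, 0.178 to 3.62), Chst1 (31.9 CPM, 0.191 to 1.06) and the mean log2 CPM of erythroid markers (2.49, the others 1.63 to 1.87). In Lmo2tg DN2/3 they were Thsd4 in replicate 5 (36.7 CPM, 0.0549 to 5.87), and Mira (0.101 CPM) and Pgr (0.0577 CPM) in replicate 2, the others at 0.

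In Ldb1-KO DN2/3, replicate 5 stood apart in Pgr (30.1 CPM, the others 0.325 to 5.24) and Ryr2 (0.857 CPM, 0.0282 to 0.269), and replicate 4 in Faxc (1.17 CPM, 0 to 0.137) and Bop1 (157 CPM, 119 to 123). In Ldb1-KO DN4, replicate 4 stood apart in Aim2 (14.2 CPM, 25.3 to 29.8) and Faxc (0.585 CPM, 0 to 0.0676), replicate 3 in Ephb4 (1.78 CPM, 0.0623 to 0.406) and Hoxa9 (8.45 CPM, 1.12 to 2.7), and replicate 2 in the mean log2 CPM of gamma-delta T markers (4.49, the others 5.82 to 6.27). In wild type DN2/3, replicate 1 stood apart in Il17rb (255 CPM, 310 to 316) and Ifi44 (3.53 CPM, 7.35 to 7.9), and replicate 4 in Sobp (0.0179 CPM, the others 0). In wild type DN4 it was replicate 3 in Heyl (1.17 CPM, 0.71 to 0.732), replicate 1 in Dkc1 (284 CPM, 318 to 324) and replicate 2 in the mean log2 CPM of thymic stroma markers (1.71, the others 1.2 to 1.29).

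The effect of the transgene differed between the stages by the test of the difference in 3684 genes. Differences (log2, DN4 minus DN2/3) among named genes were positive in Lmo2 (2.22), Kazn (3.61), Ica1 (4.35), Lyl1 (3.44), Hhex (5.30), Spib (3.24), Cd3g (1.45), Ptcra (1.25), Heyl (1.25), Cdkn1a (2.72), Btg1 (2.57), Cdkn1b (0.65), Bmf (1.99), Bcl2 (2.16), Kit (1.49), Tgfbr2 (1.74), Il17rb (1.12), Slc16a3 (1.61), Ifi44 (5.23), Ifih1 (1.59), Mx1 (2.47), Mx2 (2.16), Oasl2 (3.09), Npas2 (7.78) and Ubqlnl (8.37). They were negative in Ccnb1 (-1.57), Cenpf (-1.0), Ccne1 (-1.38), Tyms (-1.10), Mki67 (-1.11), Rrm2 (-1.11), Bop1 (-0.92), Myc (-0.75), Dkc1 (-0.63), Pgk1 (-0.92), Pfkp (-0.84), Arsi (-3.62), Pdlim4 (-3.37) and H2-Q1 (-3.11). The lists that differed were stem and progenitor regulators (adjusted p = 7.12e-09), cell cycle (1.11e-14), Myc and ribosome biogenesis (1.66e-07), interferon response (2.96e-05), glycolysis (0.000186), cytokine receptors (0.00369), T-lineage (0.0432), Notch targets (0.0467), B cell (0.0138), NK (0.0467), dendritic (0.0126), mature T (0.0155), thymic stroma (0.0138) and immediate early genes (0.0126), none of which held with an estimated correlation. Pairs as a block ended the Notch and NK calls. The call on NK markers ended without wild type DN2/3 replicate 3 (adjusted p = 0.0767), wild type DN4 replicate 1 (0.0529) or 3 (0.051), Lmo2tg DN2/3 replicate 1 (0.0524), 3 (0.0739), 4 (0.0591) or 5 (0.0559) or Lmo2tg DN4 replicate 1 (0.0579), 2 (0.0523) or 5 (0.0646), and that on mature T markers without Lmo2tg DN4 replicate 1 (0.0505).

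The effect of deleting Ldb1 differed between the stages in 195 genes, among named genes positively in Arhgap19 (1.55), E2f7 (1.36) and Ccnd3 (1.08) and negatively in H19 (-6.51), Btk (-6.26), Scin (-5.96), Npas2 (-5.57), Ica1 (-4.30), Kazn (-4.10), Cdkn1a (-3.01), Spib (-2.41), Il17rb (-1.24) and Cd3g (-0.66). The lists were stem and progenitor regulators (adjusted p = 4.32e-18), cell cycle (3.6e-16), cytokine receptors (1.2e-05), immediate early genes (9.07e-05), NK (0.000137), myeloid (0.000568), thymic stroma (0.000568), megakaryocyte (0.00167), dendritic (0.00227), B cell (0.00296), mature T (0.00427), Myc and ribosome biogenesis (0.00529), interferon response (0.00663), glycolysis (0.00829) and Notch targets (0.018). Of these, stem regulators (0.000782), thymic stroma (0.0154) and megakaryocyte markers (0.05 rounded up) held with an estimated correlation. Gamma-delta T markers did not pass (0.0596) but did with pairs as a block (0.0453) and without Lmo2tg DN2/3 replicate 2 (adjusted p = 0.0385) or 4 (0.0463), Lmo2tg DN4 replicate 2 (0.0244), Ldb1-KO DN2/3 replicate 2 (0.0423) or Ldb1-KO DN4 replicate 3 (0.0379), 4 (0.0198) or 5 (0.0373). The call on Notch targets ended without Lmo2tg DN2/3 replicate 5 (0.0727), Lmo2tg DN4 replicate 2 (0.0628) or 4 (0.207), Ldb1-KO DN2/3 replicate 4 (0.102) or Ldb1-KO DN4 replicate 2 (0.0502). That on ribosome biogenesis ended without Lmo2tg DN2/3 replicate 2 (0.0911) or Lmo2tg DN4 replicate 1 (0.131) or 3 (0.0532), on glycolysis without Lmo2tg DN4 replicate 1 (0.0561) or 3 (0.0635) or Ldb1-KO DN4 replicate 4 (0.058) and on interferon response without Lmo2tg DN2/3 replicate 4 (0.0722) or Lmo2tg DN4 replicate 1 (0.423). The B cell (0.064) and mature T calls (0.088) ended without Lmo2tg DN4 replicate 1.

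Other splits were fitted with the compared groups only. Chance is unlikely for the comparisons of genotypes, each real split being 1 of at most 2 of 100 with as many genes. For Lmo2tg against wild type the real split gave 4083 genes at DN2/3 (highest other 1428) and 4947 at DN4 (5745). For Ldb1-KO against Lmo2tg it gave 2129 (312) and 681 (0), and for Ldb1-KO against wild type 3037 (2459) and 6132 (5448). For the differences between stages it gave 2146 for the transgene (2250) and 85 for Ldb1 (0), but chance stays open, as mixed genotypes can lower the others. The highest other splits of Lmo2tg at DN4, of both comparisons of Ldb1-KO with wild type and of the transgene's difference between stages moved transgenic replicate 4 into wild type, and that of Lmo2tg at DN2/3 moved replicate 5. These keep the real group of every other library, so the real difference remains in part, and no further structure was tested. Between stages, where numbers pair the libraries, the splits that part as many pairs as the real one (8, 16 and 16) are too few for a share under 0.05. The real split gave 8442 genes in wild type, 321 in Lmo2tg and 4934 in Ldb1-KO, and the highest of these others 0 in each. Among splits that ignore the pairs (35, 100 and 100), only the real one gave as many genes. The highest others part fewer pairs and gave 3, 275 and 1620.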

How the results depend on the processing

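Leaving out genes with at least 10% shared sequence, leaving Lmo2 and Ldb1 out of the lists (51 main lists passing) and leaving out Lmo2tg DN4 replicate 1 and Ldb1-KO DN4 replicate 2, were settings added after seeing the data. No result reversed. RLE normalization left all 178 named-gene calls the same, DESeq2 177, a model of the compared groups only 167 and the replicate block 166. For Ldb1-KO against Lmo2tg at DN4, calls ended with the block on Spib (adjusted p = 0.0628), Trib2 (0.066), Cdkn1c (0.07), Slc2a3 (0.106), Hk1 (0.0623) and Oas1a (0.0781). The block also ended those of Lmo2tg against wild type on Ccnb1 (DN2/3, 0.0999) and Mx2 (DN4, 0.0614), and Ldb1 passed there at DN2/3 (0.0271). The compared groups only gave 4947 genes for Lmo2tg against wild type at DN4 (7532 in the model of all samples), 681 for Ldb1-KO against Lmo2tg at DN4 (2092), 3037 for Ldb1-KO against wild type at DN2/3 (1374), 321 for DN4 against DN2/3 in Lmo2tg (2208), and 2146 (3684) and 85 (195) for the stage differences in the Lmo2tg and Ldb1-KO effects. DESeq2 gave 389 for the last. The libraries high in Cd4 and Cd8a left out gave 2446 and 94 for those differences. The cause was not tested, but counts moved both ways and replicates differed most in Lmo2tg DN4.

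Without 1 replicate of the compared groups at a time, changed genes ranged from 3514 to 4229 and 6478 to 8336 (Lmo2tg against wild type, DN2/3 and DN4), 1730 to 2376 and 1476 to 2866 (Ldb1-KO against Lmo2tg), 764 to 1406 and 2855 to 5028 (Ldb1-KO against wild type), 5671 to 6244, 1577 to 3450 and 3116 to 3983 (stages in wild type, Lmo2tg and Ldb1-KO), and 2412 to 5411 and 139 to 624 (stage differences of the Lmo2tg and Ldb1-KO effects). A library of another group left out gave at most 4564 (Lmo2tg against wild type, DN2/3), 2625 (Ldb1-KO against Lmo2tg, DN2/3), 1677 and 5236 (Ldb1-KO against wild type), and 6999 and 4423 (stages in wild type and Ldb1-KO). Named genes passing ranged from 165 to 169 of 178, main lists from 46 to 55, markers from 36 to 44, opposite change from 35 to 47.5% at DN2/3 and 17.3 to 30.7% at DN4, and the targeted genes stayed at 4. In all 57 of 264 list results changed a call without 1 library of the compared groups, 24 of which passed with all libraries. The counts moved over 1.5 times were those without wild type DN2/3 replicate 1 (764), 3 (877) and 4 (880) and Ldb1-KO DN2/3 replicate 3 (863), wild type DN4 replicate 3 (2855), Lmo2tg DN4 replicate 4 (3450 and 624), and wild type DN2/3 replicate 2 (2412).

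With the replicate number as a block, Lmo2tg against wild type at DN4, where numbers do not pair, gave 2186 genes (69.4% higher, against 55.1%). Ldb1-KO against Lmo2tg gave 2712 at DN2/3 and 681 at DN4. With the genotype-by-number pairs as a block, the stages gave 5569 in Lmo2tg and 6934 in Ldb1-KO, and the stage differences 7106 and 1933 (46.5% higher in the last, against 9.7%). Among paired results the block also changed the calls on Lmo2 in Ldb1-KO (adjusted p from 0.0615 to 0.00861) and on myeloid (0.0307 to 0.186), Notch (0.0467 to 0.0544), NK (0.0467 to 0.0937) and gamma-delta T lists (0.0596 to 0.0453), and no other call. Main lists passing fell from 52 to 5 with an estimated correlation, and markers from 39 to 5, with 73 by fry, which asks another question. Opposite change fell from 42.4 to 25.1% and from 23 to 9.5% with the Lmo2tg libraries split, which leaves fewer libraries per comparison.

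Simulated data recovered 36.4 to 43.9% of 1.5-fold changes, so smaller ones can be missed. False calls under unequal group spread were not simulated. Folds of genes at 0 counts were bounded only by the floor of 3 counts.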

Other observations

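Tests of chromosome regions were chosen after seeing the result. Genes changed over 2-fold clustered in some 4-megabase regions (one-sided hypergeometric test against all tested genes, adjusted per comparison). At the Hoxa cluster (chromosome 6, 52 to 56 megabases) 12 of 20 genes changed in Ldb1-KO against Lmo2tg at DN2/3 (adjusted p = 8.88e-06). All rose, as did 8 at DN4 (0.0197). In Lmo2tg against wild type 12 changed at each stage, 1 higher at DN2/3 (0.00162), 2 at DN4 (0.0454). Others included a chromosome 13 histone region (24 of 62, DN2/3, 0.00162) and chromosome 7 at 104 to 108 (15 of 29, DN4, 0.0454). At 140 to 144 of chromosome 7, with imprinted H19, Igf2 and Cdkn1c, 20 of 78 changed in Ldb1-KO against Lmo2tg at DN2/3 (0.00219). So did 7 of 9 at 4 to 8 of chromosome 14 (0.000385).

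Cd4 and Cd8a transcripts were present in the DN4 samples, whose gate should leave out cells with either protein. Cd8a had 33.6 ± 16.5 CPM in wild type, 343 ± 233 CPM in Lmo2tg and 324 ± 228 CPM in Ldb1-KO, and Cd4 had 6.33 ± 3.78 CPM, 113 ± 174 CPM and 109 ± 127 CPM. The highest were Lmo2tg replicate 1 (Cd4 422, Cd8a 742 CPM) and Ldb1-KO replicate 2 (329 and 713 CPM). Xist (inactive X chromosome) was high in Lmo2tg replicate 2 and Ldb1-KO replicates 4 and 5 at both stages, with Y-linked transcripts (Ddx3y, Kdm5d, Uty and Eif2s3y) at most 0.96 CPM in sum. The other transgenic libraries had Xist at most 2.14 CPM and high Y-linked transcripts, so the transgenic groups hold both sexes. Wild type replicates 2, 3 and 4 had both, with Xist from 1241.16 and Y-linked transcripts from 33.38 CPM at DN2/3, and both at DN4 as well. Whether wild-type libraries pool animals is not given in the sources used here, so the spread between wild-type libraries need not be that between single animals.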
